A study of Homo sapiens with 3 samples.

How the data were processed

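Single-cell RNA libraries (10x 3' chemistry version 3.1, Illumina NovaSeq) of 3 samples were analysed, 1 library per group: FaDu cells with cinobufotalin, resistant cells with TPF and resistant cells with TPF and cinobufotalin. The deposited files hold raw counts of UMIs per gene and barcode, which the authors made with Cell Ranger 7.0 on hg38, per the labels and the processing notes. The gene annotation, the use of intronic reads and the use of strand are not given in the sources used here. All 58735 feature IDs were found in GENCODE release 29, which gave gene types and genomic spans. MLF1IP, a member of the S phase list, could not be matched by that symbol or through the older symbols searched, and was left out. Whether the files hold this gene under another symbol was not checked.

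The files held 6888, 6081 and 8888 barcodes in the group order above, with 167448330, 138850198 and 137553238 UMIs. Barcodes with at least 1000 UMIs, at least 500 genes and at most 20% mitochondrial UMIs were kept, which left 6123, 4862 and 7525 cells with a median of 3.80%, 3.98% and 3.72% mitochondrial and 18.7%, 13.7% and 14.2% ribosomal protein UMIs. Scrublet called 5, 7 and 0 cells doublets, 0.0817%, 0.144% and 0%, too few for the caller to have worked, so no doublets were removed and doublets remain among the cells.

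UMIs of the kept cells were summed per library and scaled to CPM, and a log2 ratio with a 95% Clopper-Pearson interval was computed per gene and pair with Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. Genes were counted at a mean of at least 10 CPM over the 3 libraries and at least 2-fold apart. At this depth the counting interval of 8140 of 8143 genes excluded a 2-fold difference between the 2 resistant libraries. With 1 library per group no test between groups was made and no dispersion could be estimated.

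Gene lists, 34 in all and fixed with the comparisons and alternatives before the data were examined, were used where at least 4 members had a mean of at least 5 CPM, which 30 did. The median log2 ratio of a list was placed among 10000 random lists matched on mean expression in 20 bins, and members were counted at 1.5-fold. Named genes followed a rule: in each pair the 12 highest and 12 lowest with a mean of at least 20 CPM, leaving out mitochondrial, ribosomal protein and clone-named genes, up to 4 members of each list, and always ATP1B1, ABCB1, TYMS, ERCC1, CDKN1A, MKI67, TP63, KRT5 and 1 more gene that is not reported here.

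Phases were called with scanpy 1.11.5 and anndata 0.12.19 from S and G2/M gene lists over all 3 libraries, each cell thinned to 5000 UMIs. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 0.5, and served description only. The gene counts and intervals were tested on simulated data, Poisson counts drawn from the pooled expression of each pair. Such counts hold no variation between cells or libraries, so the test checks the calculation at this depth only. In each pair all 50 genes simulated at 2.5-fold higher, 50 at 4-fold higher and 50 at 2.5-fold lower were recovered, 0 of 50 at 1.5-fold were called, and 0 of 8239, 7731 and 7651 unchanged genes were called, with 94.8%, 94.8% and 95.5% of intervals holding the simulated ratio. Of 1000 random lists 54, 52 and 55 lay beyond the limits.

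Alternatives fixed beforehand were all deposited barcodes, at most 10% mitochondrial UMIs, at least 2000 genes per cell, doublet calls left out, TMM factors (edgeR 4.0.16 in R 4.3.3; 0.778, 1.15 and 1.12), totals without mitochondrial and ribosomal protein genes, equal weight per cell, cells thinned to 5000 UMIs, each phase alone, and other limits on low genes, on thinning and on clustering. Chosen after the data were seen were 5 sets of cells matched between libraries on the share of MALAT1 (2% to 8% mitochondrial UMIs and at least 10000 UMIs), leaving out cells over 2 times the median UMIs of their library, random lists matched on genomic span, and list percentiles among cells called G1 and in the 5 matched sets. Free RNA was not corrected for, since barcodes without cells were not used here.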

Results

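Single-cell RNA sequencing was used to profile FaDu cells, a human squamous carcinoma line of the hypopharynx, and a subline made resistant to TPF, the combination of paclitaxel, cisplatin and 5-fluorouracil. Cinobufotalin, the other agent of the study, is a bufadienolide, a class of steroid found in toad venom. There were 3 libraries, 1 per group: FaDu cells given cinobufotalin (the FaDu cinobufotalin library), resistant cells given TPF (the resistant TPF library) and resistant cells given TPF with cinobufotalin (the resistant TPF cinobufotalin library). FaDu cells without drug or with TPF, and resistant cells without TPF, were not analysed here. In the order above, 6123, 4862 and 7525 cells with 165847771, 135176387 and 134802289 UMIs were kept, with a median of 24440, 27920.5 and 17867 UMIs and 4782, 5847 and 4668 genes per cell. No group had a replicate library, so nothing was tested between groups, an effect of the library and one of the treatment are the same comparison, and every interval is a 95% Clopper-Pearson interval that covers counting error only.

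All 11 squamous epithelial markers were measured in these libraries, among them KRT17 at 2729, 1823 and 1298 CPM (UMI counts scaled to the same total in each library) in the order above and KRT18 at 1872, 1650 and 1303 CPM. None of the 10 fibroblast and 14 immune cell markers reached a mean of 5 CPM. Of the 9 endothelial markers ERG alone did, at 9.54, 20.1 and 24.9 CPM, and of the 6 erythroid markers HBA1 alone, at 5.71, 12.1 and 9.53 CPM. MALAT1, a long noncoding RNA kept in the nucleus, made up a median of 0.0892% of a cell's UMIs in the FaDu cinobufotalin library, against 0.795% and 0.731% in the resistant TPF and resistant TPF cinobufotalin libraries. Of cells with at least 10000 UMIs, 52.3% (51.0 to 53.6) of the FaDu cinobufotalin library had MALAT1 under 0.1% of UMIs, against 8.22% (7.43 to 9.05) and 11.8% (10.99 to 12.6).

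The question of what cinobufotalin adds to TPF in resistant cells was addressed by the resistant TPF cinobufotalin library over the resistant TPF library, the only pair that differed in 1 labelled factor. LRRC75A was 2.54 times as high with cinobufotalin (log2 ratio 1.34, 1.29 to 1.40; 65.5 against 25.8 CPM) and was the only gene of 8143 at least 2-fold higher. ITGAM, the alpha M integrin subunit, was the only gene at least 2-fold lower (-1.09, -1.20 to -0.99; 8.43 against 18.0 CPM), and it was chosen after its values were seen because its mean level lies below that set for named genes. Next highest were C1orf56 (0.97), the 7SK-family transcript RF00100 (0.76), the splicing regulator HNRNPH1 (0.65, 0.62 to 0.67), the translocon subunit SEC61G (0.56), the metallothionein MT1X (0.55), KANSL1 (0.54), the complex III subunit UQCRQ (0.51), OOEP (0.50), SNHG9 (0.50), C4orf48 (0.47) and the ATP synthase subunit ATP5MC1 (0.46). The lowest were ARC, an immediate early gene (-0.81, -0.88 to -0.74), PLSCR2 (-0.74), the cytidine deaminase APOBEC3B (-0.65), PACSIN3 (-0.65), FKBP8 (-0.61), GIPC1 (-0.60), the interferon-induced IFIT1 (-0.59, -0.62 to -0.57), IGFBP7 (-0.59), CORO1B (-0.58), the myosin light chain MYL9 (-0.56), ANKRD12 (-0.55) and ZNF165 (-0.55). For 8140 of the 8143 genes the counting interval excluded a 2-fold difference. Of the 8143 genes 75.1% had an interval that excluded 0, so such an interval was usual in this pair and does not set a gene apart.

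In this pair 10 of 30 gene lists with at least 4 measured members had a median beyond the central 95% of 10000 random lists. The random lists were of matched expression, and 1.5 would be beyond if the lists were random draws of genes. Members of a list can move together and some lists share genes, so more than 1.5 can lie beyond without an effect of cinobufotalin. Nuclear-encoded respiratory chain genes were higher with cinobufotalin, with a median log2 ratio of 0.20 over 39 members against 0.018 for random lists (percentile 100), led by UQCRQ, ATP5MC1, COX8A (0.45) and UQCR10 (0.43), and none of the 39 reached 1.5-fold. The 4 measured metallothioneins, small metal-binding proteins, had a median of 0.25 (percentile 99.3), with MT1E at 0.27 and MT2A at 0.23. Homologous recombination and crosslink repair genes had a median of 0.050 (percentile 99.8) and stemness-associated genes one of 0.078 (percentile 98.4).

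Tubulins and taxane-related genes were the list furthest below its random lists, with a median of -0.21 over 14 members (percentile 0.060), and TUBA1C (-0.55), TUBB2A (-0.50), TUBB4B (-0.47) and TUBA1B (-0.45) as its largest differences. Interferon-stimulated genes had a median of -0.15 over 35 members (percentile 0.22), with XAF1 at -0.51, the transcription factor IRF7 at -0.47 and OASL at -0.41 beside IFIT1. MHC class I antigen presentation genes had a median of -0.18 (percentile 0.30), with the peptide transporter TAP1 at -0.39 and HLA-E at -0.34. Immediate early genes (-0.13, percentile 0.99; JUNB -0.48, but EGR1 0.39), heat shock proteins (-0.14, percentile 1.99; DNAJA1 -0.33, HSPA8 -0.32) and glycolysis enzymes (-0.14, percentile 2.0; PKM -0.27) were also low, but lay at percentiles 4.3, 4.81 and 2.70 among random lists matched on gene span too. ATP1B1 was at 0.11 (0.070 to 0.15). The cell cycle inhibitor CDKN1A was at -0.016, the squamous master regulator TP63 at -0.029, the 5-fluorouracil target TYMS at -0.097, ERCC1 of nucleotide excision repair at -0.23, the proliferation marker MKI67 at -0.27 and the basal keratin KRT5 at -0.28. ABCB1, the P-glycoprotein efflux pump, was at 3.35 against 2.94 CPM, below the level set for list members. Among other lists inside the limits in all kept cells were some tied to the drugs or to cell death, with medians of -0.025 (percentile 67.0) for multidrug efflux transporters, -0.090 (22.4) for fluoropyrimidine metabolism, -0.060 (44.0) for platinum transport and nucleotide excision repair, -0.097 (19.1) for BCL2 family and apoptosis regulators and -0.087 (24.3) for p53 target genes.

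LRRC75A overlaps LRRC75A-AS1, an antisense gene at a mean of 684 CPM, and C1orf56 overlaps CDC42SE1 at 71.7 CPM, so these levels are uncertain where counting did not use strand, which is not given in the sources used here. With the level for counted genes lowered to a mean of 1 CPM, 12 genes were at least 2-fold higher and 7 lower out of 14656. Over 5 sets of cells matched between libraries on MALAT1, 2 to 17 genes were higher and 0 to 111 lower. Both maxima were at 0% to 0.05% MALAT1, where 75 resistant TPF cells were left. ITGAM was counted as lower only in the set at 1% to 2%. It was not so counted with equal weight per cell, in cells thinned to 5000 UMIs or in cells called S. Of the 10 lists only tubulins stayed beyond the limits in each of those 5 sets (percentiles 0 to 1.81). Respiratory chain genes spanned 96.2 to 100 and interferon-stimulated genes 0 to 51.0, while metallothioneins were inside the limits in all 5, at 93.7 to 97.3. Among cells called G1, respiratory chain genes stayed at percentile 100, but tubulins were at 4.07, glycolysis enzymes at 41.1 and stemness-associated genes at 87.1, inside the limits.

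**Figure D1:**
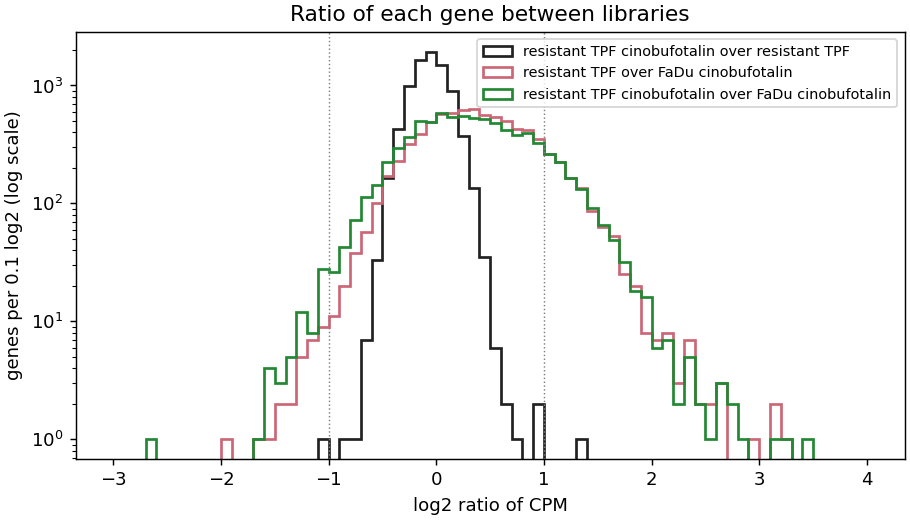
Histogram of the log2 ratio of CPM of each of 8143 genes with a mean of at least 10 CPM, for the 3 pairs of libraries, with the number of genes per 0.1 on a log axis and dotted lines at a 2-fold difference. The central 95% of genes lay between -0.40 and 0.29 in resistant TPF cinobufotalin over resistant TPF, and between -0.55 and 1.5 in resistant TPF over FaDu cinobufotalin.

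The resistant TPF library was then compared with the FaDu cinobufotalin library, which differs from it in line and in drug, so the pair does not separate resistance from either treatment. TXNIP, an inhibitor of thioredoxin and of glucose uptake, was at 167 against 18.3 CPM, a log2 ratio of 3.19 (3.14 to 3.25) and 2.82 above the median gene. The histone genes HIST1H2AM (3.23, 3.12 to 3.34), HIST1H1D (3.11), HIST1H1B (2.40) and HIST1H1E (2.38) were also among the 12 highest, with MORC4 (2.45), SH3GL2 (2.34), the guidance ligand SLIT2 (2.30), the DNA primase subunit PRIM1 (2.25), the recombination mediator BRCA2 (2.25, 2.17 to 2.32), the cell cycle repressor E2F8 (2.24) and FAM111B (2.19). Among the 12 lowest were LY6D at -1.49 (-1.56 to -1.41) and the basal keratin KRT15 at -1.38 (-1.45 to -1.31), and KRT5 was at 76.2 against 151 CPM (-0.98, -1.02 to -0.95), while the adhesion protein CDH1 was at 163 against 98.6 CPM. The remaining lowest genes were IGFL2-AS1 (-1.62), IGFL1 (-1.59), ASB2 (-1.35), the interferon-induced membrane protein IFITM1 (-1.22), the long noncoding RNA UCA1 (-1.19), HCFC1R1 (-1.16), the ATP synthase subunit ATP5F1D (-1.16), S100A10 (-1.15), CCDC85B (-1.13) and REX1BD (-1.09).

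Of 8143 genes, 1078 were at least 2-fold higher and 28 at least 2-fold lower in the resistant TPF library, and the median gene was at 0.37. With TMM scaling the median gene was at -0.20, 146 genes were higher and 377 lower, or 27.9% higher, so the balance of directions depended on the scaling. TXNIP was then at 2.63, HIST1H2AM at 2.66, KRT15 at -1.95 and KRT5 at -1.55. Over the 5 sets of matched cells 363 to 416 genes were higher and 20 to 97 lower. At 0.3% to 1% MALAT1 these were 365 and 35, with TXNIP at 2.80, BRCA2 at 2.0 and KRT5 at -1.21. SLIT2 was at 1.15 against 2.30 in all kept cells.

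Cell cycle and recombination genes were higher in the resistant TPF library than random lists of matched expression, and percentiles among random lists do not move with the scaling, though counts of members do. Of 41 measured S phase genes 28 were at least 1.5-fold higher and none lower, with a median of 0.93 against 0.37 for random lists (percentile 100), among them CASP8AP2 (2.13) and cyclin CCNE2 (1.83). Of 52 G2 and M phase genes 31 were higher and none lower, with a median of 0.71 (percentile 100), among them CKAP2 (1.57) and MKI67 (1.54, 1.5 to 1.59). Of 29 homologous recombination and crosslink repair genes 23 were higher and none lower, with a median of 0.88 (percentile 99.97), led by RAD50 of the MRE11 complex (2.41), BRCA2, PALB2 (1.67) and RAD51B (1.79, but -0.10 in cells matched at 0% to 0.05% MALAT1). With TMM scaling 18 S phase genes were higher and 0 lower, 9 G2 and M phase genes higher and 9 lower, and 10 recombination genes higher and 1 lower. In the cells matched at 0.3% to 1% MALAT1 the 3 medians were 0.83, 0.59 and 0.73, each at percentile 100. Over the 5 matched sets the recombination list spanned percentiles 98.6 to 100. Among cells called G1 they were 0.14, 0.062 and 0.47, at percentiles 2.10, 0.31 and 60.6, where the calls rest on the S and G2/M lists themselves. The list named nuclear-retained RNAs, NORAD among its members, was higher as well (median 0.85, percentile 99.7, MALAT1 1.85 and NEAT1 0.87). MALAT1 was at 9798 against 2710 CPM. Where the other members lie in the cell was not checked, so the median need not measure nuclear RNA alone. The higher median was lost in all 5 matched sets, at percentiles 50.9 to 85.7, in part by construction as MALAT1 is 1 of the 4 members. NEAT1, which was not matched, was at -0.89 to -0.042 in them.

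Glycolysis enzymes lay at a median of -0.21 against 0.24 for random lists (percentile 0.030), with the lactate exporter SLC16A3 at -0.72, the glucose transporter SLC2A1 at -0.68 and GAPDH at -0.67, while SLC2A3 was at 0.75, and at -0.15 in cells matched at 0% to 0.05% MALAT1. Cholesterol synthesis genes had a median of -0.0092 against 0.43 (percentile 0.010), and none of the 23 reached 1.5-fold, but 11 were at least 1.5-fold lower with TMM scaling. Of 4 metallothioneins 2 were at least 1.5-fold lower, MT1E (-0.96) and MT2A (-0.69), with a median of -0.56 (percentile 0.28), and all 4 were with TMM scaling. MHC class I genes had a median of -0.15 against 0.19 (percentile 0.78), with PSMB10 at -0.86 and B2M at -0.28. In the cells matched at 0.3% to 1% MALAT1 these 4 lists stayed low, with medians of -0.094, -0.11, -0.41 and -0.24 at percentiles 0.34, 0.020, 0.99 and 0.060. Metallothioneins were at up to percentile 12.2 in the other matched sets and MHC class I genes were at 5.98 among cells called G1. Respiratory chain genes (-0.18, percentile 2.09) and keratinocyte differentiation genes (-0.023, percentile 0.95; KLK10 -0.67, DSC2 1.61) did not stay low in those cells, at percentiles 12.2 and 6.94, and the latter list was at percentile 15.4 when random lists were matched on gene span too. Lists of multidrug efflux transporters (0.14, percentile 7.71), fluoropyrimidine metabolism (0.30, percentile 39.0) and p53 target genes (0.48, percentile 71.2) lay inside the limits in all kept cells. Efflux transporters were beyond them at percentile 1.48 with gene span matched and 1.06 in the cells at 0.3% to 1% MALAT1, and fluoropyrimidine metabolism at 0.020 among cells called G1 (median -0.19).

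**Figure D2:**
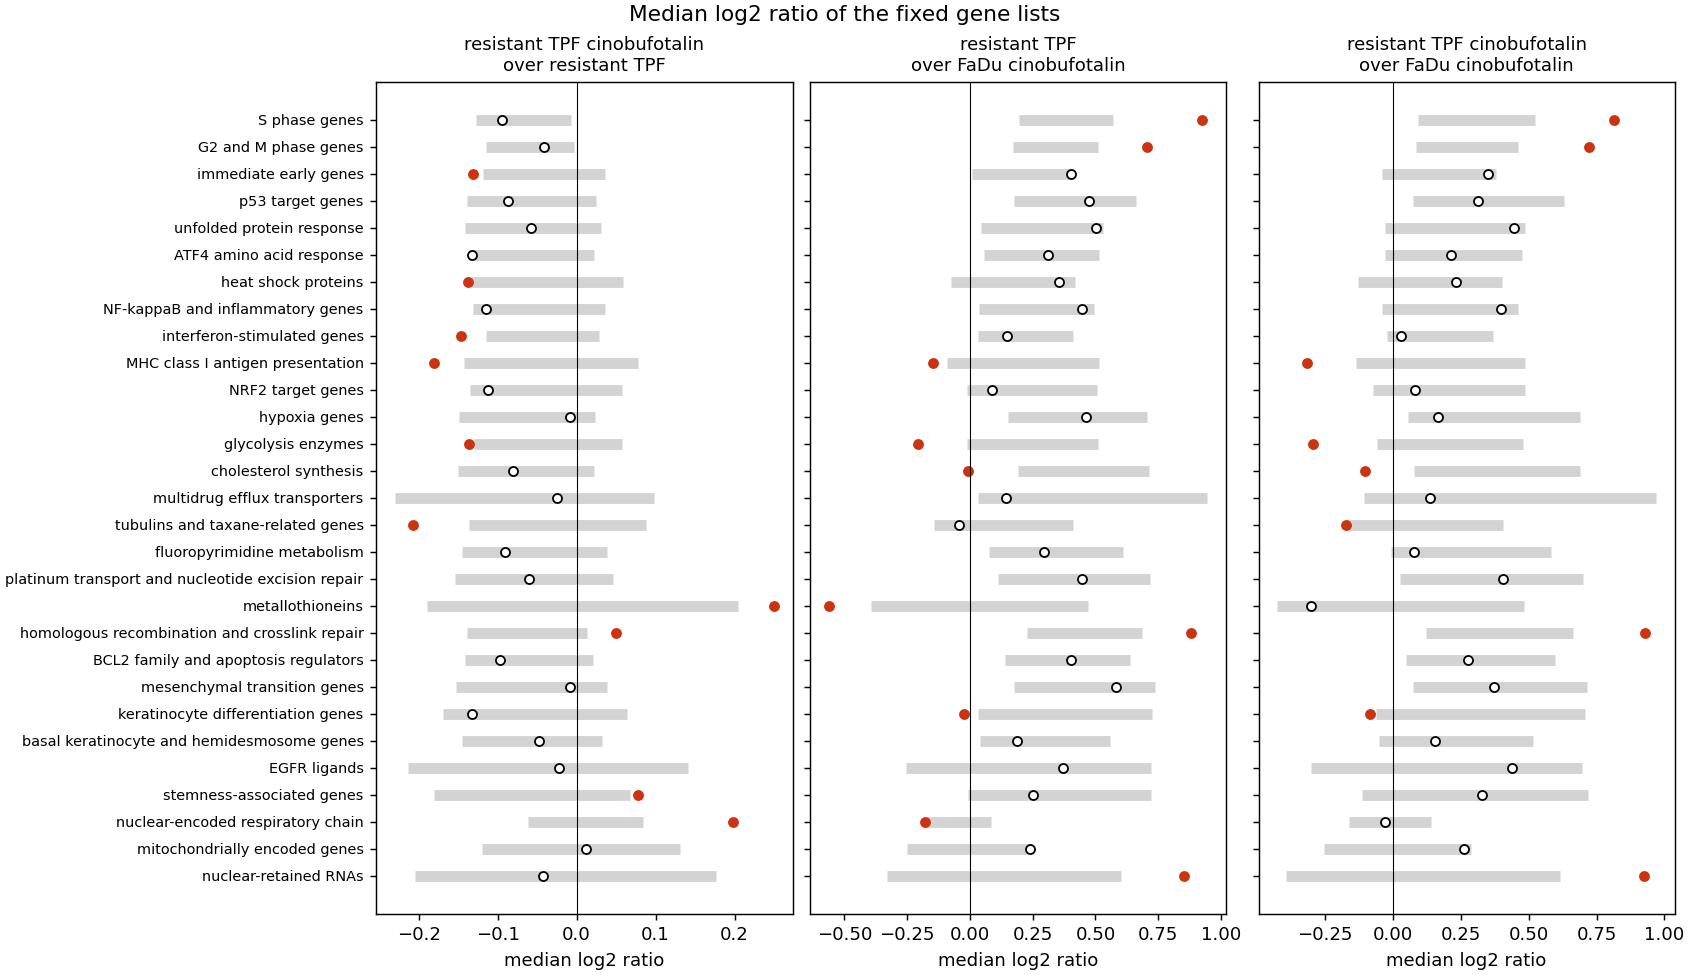
Median log2 ratio of CPM of 29 fixed gene lists (points) in the 3 pairs of libraries, with the central 95% of 10000 random lists of matched expression as grey bars and filled points where the median lies beyond them. S phase genes lay at 0.93 and 0.82 in resistant TPF and resistant TPF cinobufotalin over FaDu cinobufotalin, and tubulins at -0.21 in resistant TPF cinobufotalin over resistant TPF.

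Lists of tubulins (-0.044, percentile 11.7) and of platinum transport and nucleotide excision repair (0.45, percentile 66.4) lay inside the limits too. The genes that follow are single genes. DPYD, which degrades 5-fluorouracil, was at 28.5 against 7.85 CPM (1.86, 1.77 to 1.95), but at 1.04 in cells matched at 0.3% to 1% MALAT1 and at -0.13 in those matched at 0.05% to 0.2%. RRM1, a subunit of ribonucleotide reductase, was at 1.32 (1.27 to 1.37) and REV3L, the catalytic subunit of translesion polymerase zeta, at 1.65 (1.59 to 1.71). ABCB1 was at 2.94 against 0.989 CPM (1.57, 1.31 to 1.85), under the level for list members. TUBB, the main beta tubulin, was at -0.67. TYMS was at 0.29 and turned to -0.28 with TMM scaling, CDKN1A at 0.18 and turned to -0.39, TP63 at 0.33 and turned to -0.24, and ATP1B1 at 0.060 and turned to -0.51. ERCC1 was at -0.20 (-0.24 to -0.16).

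**Figure D3:**
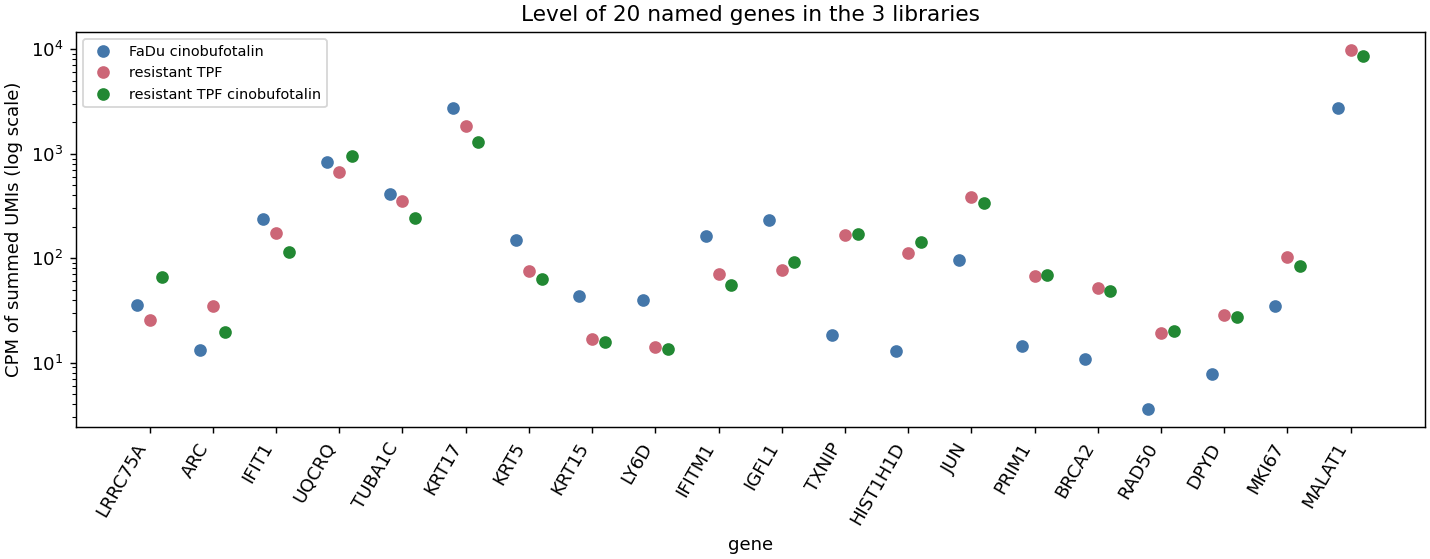
CPM of summed UMIs (log axis) of 20 named genes in the 3 libraries, 1 point per library. TXNIP lay at 18.3, 167 and 171 CPM and KRT15 at 43.5, 16.7 and 15.7 CPM in FaDu cinobufotalin, resistant TPF and resistant TPF cinobufotalin.

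The resistant TPF cinobufotalin library over the FaDu cinobufotalin library compared cells that had both received cinobufotalin and differed in line and in TPF. The highest genes were HIST1H1D (3.45, 3.39 to 3.52), TXNIP (3.23, 3.18 to 3.29), HIST1H2AM (3.16), HIST1H1E (2.61), SH3GL2 (2.35), MORC4 (2.34), SLIT2 (2.32), HIST1H1B (2.28, but -0.25 in cells matched at 0% to 0.05% MALAT1), PRIM1 (2.27), BRCA2 (2.16), MYO16 (2.15) and E2F8 (2.12). The lowest 12 held LY6D (-1.54), the 14-3-3 protein SFN (-1.27), the keratins KRT15 (-1.47), KRT5 (-1.26, -1.30 to -1.23), KRT14 (-1.23) and KRT19 (-1.22), and IFITM1 (-1.59), IGFBP7 (-1.48), ASB2 (-1.40), IGFL1 (-1.32), CCDC85B (-1.27) and ABHD14B (-1.22). S phase genes had a median of 0.82 with 26 of 41 at least 1.5-fold higher, G2 and M phase genes 0.72 with 31 of 52, homologous recombination genes 0.93 with 23 of 29, and nuclear-retained RNAs 0.92 (percentiles 100, 100, 100 and 99.9). With TMM scaling 15 S phase, 10 G2 and M phase and 11 recombination genes were higher, and 1, 7 and 0 lower. MHC class I genes (-0.31, percentile 0.070; PSMB10 -1.05), glycolysis enzymes (-0.29, percentile 0.010), cholesterol synthesis genes (-0.10, percentile 0.080), keratinocyte differentiation genes (-0.084, percentile 1.83) and tubulins (-0.17, percentile 2.5) lay low. Basal keratinocyte and hemidesmosome genes lay inside the limits (0.16, percentile 33.8). The list named nuclear-retained RNAs was at percentiles 48.1 to 75.4 over the 5 matched sets, in part by construction. In the cells at 0.3% to 1% MALAT1, keratinocyte differentiation genes were at percentile 16.2 and tubulins at 3.83, and among cells called G1 the S, G2/M and recombination lists were at 17.5, 54.7 and 97.2, all inside the limits. Keratinocyte differentiation genes were at percentile 21.5 with gene span matched. DPYD was at 1.80, ABCB1 at 1.76, MKI67 at 1.27 and ERCC1 at -0.43. ATP1B1 was at 0.17, TP63 at 0.30, TYMS at 0.19 and CDKN1A at 0.16, and these 4 turned to -0.35, -0.22, -0.33 and -0.36 with TMM scaling.

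At least 2-fold higher were 1087 genes and lower 62 in this pair, or 94.6% higher with the median gene at 0.31, against 187 higher and 508 lower with TMM scaling, or 26.9% higher with the median gene at -0.22. In cells matched at 0.3% to 1% MALAT1, 420 were higher and 69 lower. At 0.05% to 0.2% these were 273 and 163, and at 0% to 0.05% 283 and 374, so the balance turned. The 2 comparisons against the FaDu cinobufotalin library shared 905 higher and 23 lower genes, where independent lists would share 143.9 and 0.213 and simulated libraries without any difference shared 0 and 0. The simulation held counting error only, which hardly gives 2-fold differences at this depth. Neither figure is a baseline for the overlap, since the 2 comparisons share a library and are not independent. Their ratios correlated across genes, which are not independent replicates, at 0.954 against 0.461 in the simulation, with a covariance of 0.295 against 0.000632, and part of this comes from the shared library, which could not be split.

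Phase calls placed 10.4% (9.59 to 11.2) of FaDu cinobufotalin cells in S, against 24.3% (23.1 to 25.6) of resistant TPF and 22.5% (21.6 to 23.5) of resistant TPF cinobufotalin cells. In G2/M were 57.1% (55.8 to 58.4), 56.0% (54.6 to 57.4) and 57.7% (56.5 to 58.8). Each cell was thinned to 5000 UMIs for this, which left out 144, 205 and 571 shallower cells. Without thinning the shares in S were 13%, 31.9% and 31.6%. When each library was scored by itself the FaDu cinobufotalin share in S was 38.9%, so the order of the libraries rested on scoring them together, and free RNA in the droplets was not measured. Unsupervised clustering gave 8 clusters, of which the largest held 5326 FaDu cinobufotalin cells among its 5677.

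**Figure D4:**
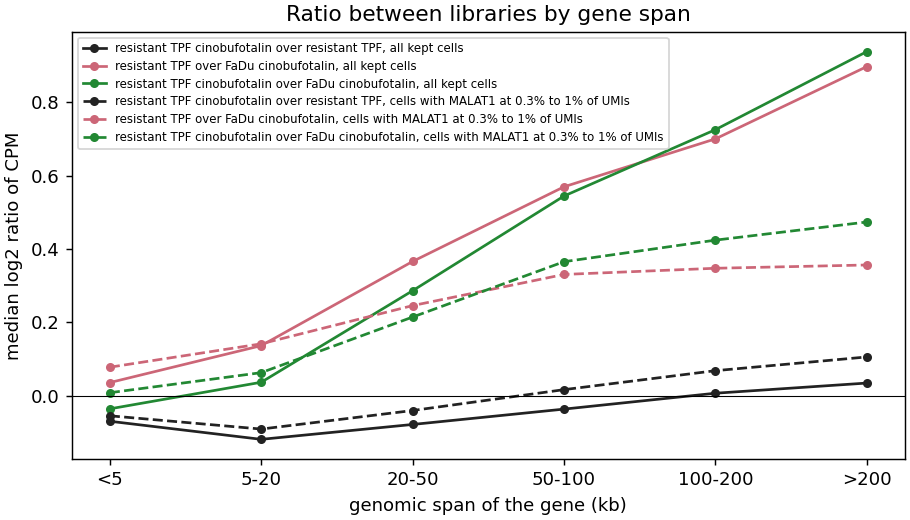
Median log2 ratio of CPM by the genomic span of the gene, in 6 bins from under 5 kb to over 200 kb, for the 3 pairs of libraries over all kept cells (solid lines) and over cells with MALAT1 at 0.3% to 1% of UMIs (dashed lines). In resistant TPF over FaDu cinobufotalin the median was 0.036 for genes under 5 kb and 0.90 for genes of at least 200 kb.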

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

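The tests of nuclear RNA below, with the 5 sets of cells matched on MALAT1, were chosen only after the results were seen.

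Barcodes with over 20% mitochondrial UMIs lay outside the kept cells, so the results above do not rest on them, and they entered only the alternative with all deposited barcodes. They made up 10.0% of the deposited barcodes of the FaDu cinobufotalin library (9.30 to 10.7), 17.5% of the resistant TPF library (16.6 to 18.5) and 13.3% of the resistant TPF cinobufotalin library (12.6 to 14.0). The difference between libraries was not tested.

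Long genes were higher than short genes in the resistant TPF library over the FaDu cinobufotalin library: the median log2 ratio of genes of at least 200 kb minus that of genes under 5 kb was 0.86. A difference in UMIs per cell was predicted to lose this when cells were thinned to 5000 UMIs, but 0.825 remained. Random thinning leaves the expected mix of genes in each cell unchanged and only reweights cells. The test therefore cannot exclude a cause tied to UMIs per cell. Less nuclear RNA per droplet in the FaDu cinobufotalin library may be part of the cause, since the difference was at most 0.359 in the 5 sets of cells matched on MALAT1. Whether it is the whole cause cannot be told apart from a part, because the sets ranged from 0.140 to 0.359, on either side of the limit set for it. In resistant TPF cinobufotalin over FaDu cinobufotalin, with the same FaDu library, 0.199 to 0.528 was left over the 5 sets, more than in the pair above in 4 of them. Over all kept cells the difference was 0.97 in that pair and 0.10 in resistant TPF cinobufotalin over resistant TPF, which argues against an effect of cinobufotalin that is the same in both lines. An effect of UMIs per cell, of the line, of TPF, of cinobufotalin in FaDu cells alone, or of the single FaDu cinobufotalin library remains open.

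The 1078 genes at least 2-fold higher in the resistant TPF library, TXNIP and BRCA2 among them, had a median log2 ratio of 1.22. Nuclear RNA as the whole cause would have brought this under a limit in each matched set. The highest of the 5 medians was instead 0.852 and the lowest 0.786. That argues against nuclear RNA as the whole cause but does not exclude it. The genes were chosen as higher in these same cells, and a shared MALAT1 range need not make nuclear RNA equal. With TMM factors their median over all kept cells was 0.66. A larger share of S phase cells as the whole cause would have lowered the median among cells called G1, but it was 1.23. The calls rest on scoring the libraries together (10.4% of FaDu cinobufotalin cells in S, but 38.9% when scored alone). That test therefore cannot exclude this cause for these genes. Of these genes 905 were also 2-fold higher in resistant TPF cinobufotalin over FaDu cinobufotalin, where both libraries had cinobufotalin, and the 2 resistant libraries had 1 gene higher and 1 lower with it, which argues against an effect of cinobufotalin shared by the lines. Nuclear RNA as part of the cause, an effect of the single FaDu cinobufotalin library, the line, TPF, or cinobufotalin in FaDu cells alone remains open.

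Few genes were 2-fold apart between the 2 resistant libraries, LRRC75A and ITGAM alone. A library deposited more than 1 time could have produced this, but only 19 barcodes were found in both, against 15.7 from the rate between the lines. Too few counts could have hidden differences, but for 99.96% of genes the counting interval excluded a 2-fold difference. A small effect of cinobufotalin on resistant cells remains open.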

How the results depend on the processing

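The 5 sets of cells matched on MALAT1, the removal of cells over 2 times the median UMIs, and list percentiles in G1 and matched cells were chosen only after the results were seen. No paired analysis was possible because each group held 1 library. Of the counts of genes 67 were within 1.5 times their value and 47 were not. Of 7276 log2 ratios of named genes 200 took the other sign, 38 of them with TMM factors, and 35 of the 200 were of genes with a ratio of at least 1.5-fold and an interval without 0. Of 1707 list medians 197 took the other sign, 42 of them with TMM factors, and 27 of the 197 were of lists beyond the limits. Only these 35 and 27 are listed below. Clusters numbered 4 at resolution 0.3 and 12 at 1. Except where the setting itself selects what is measured, the cause was not tested. Depth limits the set at 0% to 0.05% MALAT1, which held 75 resistant TPF cells. Below, RC, RT and FC stand for the resistant TPF cinobufotalin, resistant TPF and FaDu cinobufotalin libraries, and counts are of genes 2-fold higher and lower.

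TMM factors gave 2 higher in RC over RT, 146 and 377 in RT over FC, and 187 and 508 in RC over FC, by their shift of every ratio. At a mean of 1 CPM there were 12 and 7, 2672 and 55, and 2639 and 123, and at 50 CPM 0 and 0, 227 and 15, and 208 and 29, from more or fewer genes. In RC over RT, equal weight per cell gave 2 and 0, thinned cells 0 lower, G1 cells 2 and 7, S cells 0 lower and G2/M cells 3 higher. In RT over FC, S cells gave 671 higher. Matched cells at 0% to 0.05% MALAT1 gave 17 and 111 in RC over RT, 416 and 97 in RT over FC, and 283 and 374 in RC over FC. At 0.05% to 0.2% these were 3 and 4, 386 and 57, and 273 and 163. At 0.3% to 1%, 2, 365 and 420 were higher. At 0.5% to 1.5% the higher were 2, 363 and 429, with 0 lower in RC over RT. At 1% to 2% the higher were 2, 377 and 448.

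Genes at least 1.5-fold higher turned to lower as follows. At 0% to 0.05% MALAT1 in RT over FC, MAP2 was at -0.087, PLOD2 -0.18, ABCC5 -0.054, ABCA1 -1.34, NEAT1 -0.75, ABCC2 -0.16, SLC2A3 -0.15, RAD51B -0.10 and HBA1 -0.25. In RC over FC, KDM3A was at -0.28, MAP2 -0.49, HIST1H1B -0.25, ABCA1 -0.18, NEAT1 -0.27, HBA1 -0.69, BRIP1 -0.12 and NORAD -0.0066. At 0.05% to 0.2% in RT over FC, DPYD was at -0.13, ERAP1 -0.036, NEAT1 -0.89, ABCC2 -1.38, ERG -0.35 and MT-ATP8 -0.14. In RC over FC, ERAP1 was at -0.38, ABCA1 -0.22, NEAT1 -0.36 and NORAD -0.018. In RT over FC, NEAT1 was at -0.23 and ABCC2 at -0.17 at 0.3% to 1%, and at -0.094 and -0.018 at 0.5% to 1.5%. At 1% to 2% NEAT1 was at -0.042 and MALAT1, matched by construction, at -0.0079, and at -0.023 in RC over FC. RRM2 was at -0.29 in G1 cells in RT over FC.

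Medians of lists beyond the limits turned too. Cholesterol synthesis in RT over FC was at 0.035 in thinned cells, 0.070 in G1, 0.040 in G2/M and 0.012 without cells over 2 times the median UMIs. Tubulins in RC over FC were at 0.083 at 0.5% to 1.5% MALAT1 and 0.16 at 1% to 2%. Homologous recombination in RC over RT was at -0.22 at 0% to 0.05% and -0.080 at 0.05% to 0.2%, and respiratory chain genes in RT over FC at 0.13 and 0.095. Stemness genes in RC over RT were at -0.013 in G1 and -0.013 at a mean of 1 CPM. Keratinocyte differentiation in RT over FC was at 0.16 with equal weight per cell, 0.42 in G1, 0.20 in S, 0.20 without cells over 2 times the median and 0.19 at a mean of 20 CPM, and at 0.47, 0.43, 0.026 and 0.14 in the 4 lower MALAT1 sets. In RC over FC it was at 0.32 in G1, 0.053 without cells over 2 times the median, and 0.76, 0.080, 0.068 and 0.040 in those sets.

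Shares of cells in S and G2/M were, at 3000 UMIs, 8.11% and 46.0% in FC, 22.4% and 51.3% in RT, and 52.2% G2/M in RC. At 10000 UMIs they were 14.3% and 58.6%, 35.5% and 48.9%, and 35.6% and 50.6%. Without thinning they were 13% and 65.7%, 31.9% and 53.2%, and 31.6% and 54.8%. Scored within each library, FC had 38.9% and 43.2%, and G2/M held 54.5% of RT and 53.5% of RC.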

Other observations

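The comparisons in matched cells in the next paragraph were chosen only after the results were seen. The test of cells in other clusters and its limits were fixed before its result, without a rule for the spread of positions.

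Genes of the basal keratinocyte layer and interferon-stimulated genes lay inside the limits in all kept cells of the resistant TPF over the FaDu cinobufotalin library (medians 0.19 and 0.15, percentiles 23.2 and 28.1). In each of the 5 sets of cells matched on MALAT1 their percentiles were 0 to 4.99, the highest of which lies inside the limits, and 0 to 0.91, but among cells called G1 they were 69.0 and 88.3. At 0.3% to 1% MALAT1 the basal list had a median of -0.18 (percentile 0.010) and the interferon list one of -0.0069 (percentile 0.91). In the resistant TPF cinobufotalin over the FaDu cinobufotalin library the 5 sets gave 0 to 0.34 and 0 to 0.275.

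A cluster of 679 cells, 126, 248 and 305 from the FaDu cinobufotalin, resistant TPF and resistant TPF cinobufotalin libraries, was marked by type III interferons. IFNL1 was at 1101 CPM against 26.5 elsewhere, IFNL3 at 159 against 1.69 and the chemokine CCL5 at 474 against 32.7. The interferon-induced IFIT2 and the RNA sensor IFIH1 were at 1250 against 183 and 181 against 30.8 CPM. These genes were chosen after their values were seen, from the 10 genes with the highest ratio in the cluster.

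In resistant TPF over FaDu cinobufotalin, JUN of the AP-1 family was at 387 against 96.4 CPM (2.01, 1.98 to 2.03), the stress factor DDIT3 at 1.48, the chaperone HSPA5 at 1.16, the matrix protease MMP3 at 32.3 against 8.34 CPM (1.96) and the cytokine IL32 at 1.60. Their lists lay inside the limits in all kept cells, with immediate early genes at percentile 97.0, the unfolded protein response at 96.0, NF-kappaB and inflammatory genes at 94.8 and mesenchymal transition genes at 82.2. With gene span matched the former 3 were beyond them, at 99.99, 99.2 and 99.8, but in the cells at 0.3% to 1% MALAT1 they were at 83.9, 85.8 and 99.93, and over the 5 matched sets NF-kappaB genes spanned 80.6 to 99.95, immediate early genes 16.2 to 94.9 and the unfolded protein response 78.8 to 92.0.

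Of FaDu cinobufotalin cells, 625 lay in clusters filled by the resistant libraries. The median MALAT1 in these clusters was 1.29%, 0.781%, 0.108% and 0.935% of UMIs, against 0.0707% in the largest cluster, filled by FaDu cinobufotalin cells. FaDu cells with more nuclear RNA could therefore lie there, which was not tested. Resistant cells among the FaDu cinobufotalin library may also be a cause. They were tested with 24 genes placed between resistant TPF cells of those clusters (0) and the other FaDu cinobufotalin cells (1). The median position was 0.802 (quartiles 0.54 to 0.996). That is past the limit of 0.75 set against resistant cells as the cause, but by less than the spread, which was no part of the limit. That cause stays open. FaDu cinobufotalin cells in the separate clusters had medians of 0.977, 0.454, 0.774 and 0.560. Resistant TPF and resistant TPF cinobufotalin cells that lay in the largest cluster were at 0.488 and 0.491. The scale therefore followed the cluster as well as the library. Some of the 24 genes, TXNIP and MMP3 among them, were also leading genes of the cluster at 0.454. The test thus cannot identify resistant cells.

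Along the genome in cells matched at 0.3% to 1% MALAT1, with the median of all genes subtracted, the lowest of 165 windows of neighbouring genes was on chromosome 19 (-0.44 in resistant TPF and -0.53 in resistant TPF cinobufotalin over FaDu cinobufotalin). The highest medians were 0.33 on chromosome 5 in the former pair and 0.37 on chromosome 1 in the latter. Beyond the limits of 1000 shuffles were 2 windows above and 9 below in the former pair, and 3 above and 13 below in the latter. In resistant TPF cinobufotalin over resistant TPF, of the same line, 0 were above and 8 below. Shuffled windows held 50 genes, but the highest on chromosome 1 held 30, so the limits were too tight for it. Shuffling also ignored gene span. Long genes still lay above short ones by 0.28, 0.47 and 0.16 in these cells and pairs. The counts cannot be told apart from that trend.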
